A study of Mus musculus with 6 samples.

How the data were processed

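RNA was measured in intestinal epithelial cells of wild-type mice on normal chow, per the labels' protocols. From 8 weeks of age the mice were given Akkermansia muciniphila (Akk, a mucus-degrading gut bacterium; 400000000 bacteria daily) by gavage for 7 weeks, or the carrier PBS. There were 3 Akk and 3 PBS libraries, numbered 1 to 3 in each group by the labels. The labels do not say that each library came from its own mouse, so p-values measure the spread between these samples, which could in part be technical.

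Per the labels' protocols, total RNA was extracted with Trizol and an Illumina mRNA library was made; the submitters' processing notes name the mm10 build. Aligner, counting program, annotation, strand setting and statistical test are not given in the sources used here. The authors deposited a single table with whole-number read counts and FPKM (fragments scaled to gene length and sequencing depth) for each of the 6 libraries, per the file headers. The authors' deposited table also gives a p-value and a log2 fold change of Akk over PBS for each gene. The header does not say whether that p-value is adjusted.

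The table holds 1386 genes and loci, of which 346 are marked higher and 1040 lower in Akk. The largest of the authors' deposited p-values is 0.0498 and the smallest fold is 1.50 in either direction, so the table holds only genes that passed a threshold on these same 6 libraries. A test of these genes on the same libraries is therefore not independent evidence, the direction of each was fixed by that choice, and no enrichment against the whole transcriptome could be computed. A gene that is not listed missed the authors' thresholds or was not measured, and these cannot be separated. Of the 1386 entries, 1322 have an Ensembl identifier, and all 1322 were found in the GENCODE M21 annotation of GRCm38 (the assembly that mm10 names), from which coordinates were taken. The other 64 are loci numbered by the authors without a gene name. Left out were 2 lines that hold only annotation text. A single gene name that a spreadsheet had turned into a date was restored by its identifier. Reads of near-identical genes, above all the defensin (Defa) genes, could have been split between copies by the counting, so their single values are uncertain.

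Column totals of such a table are not library depth. Depth was recovered from the ratio of count to FPKM, which within a gene is proportional to the depth the authors divided by, over 560 genes with a count of at least 200; absolute depth also used the exon length of 548 of them. The implied depth was 26074963, 23561991 and 27452363 fragments for PBS replicates 1 to 3. It was 29374751, 27563206 and 25858879 for Akk replicates 1 to 3. For 9 genes the log2 ratio of mean FPKM and the fitted log2 fold change of the counts lay more than 0.5 apart.

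Counts were tested with edgeR 4.0.16 (quasi-likelihood F test, filterByExpr, R 4.3.3), Akk against PBS, without a replicate term. The recovered depth served as library size, and Benjamini-Hochberg adjustment ran over the listed genes at 0.05. A count given as adjusted over the list alone was adjusted over the listed members of that list only, which the authors had selected. A list with a single listed member thus keeps its unadjusted p. TMM factors had been chosen before the data were examined, but they assume that most genes do not differ, which a table of selected genes breaks. TMM was therefore run as an alternative. RLE and upper-quartile factors computed from the listed genes share this limit. Most listed genes were lower, so RLE and TMM factors (4.39 and 4.00 for PBS replicate 2) draw these genes toward or past 0 and raise the higher ones. Gene lists with at least 5 listed members were tested against the other listed genes with limma 3.58.1 camera (preset inter-gene correlation of 0.01, voom log2 CPM). Fry, an alternative, tests a list against no change instead, which the selection of its members by direction favours. The 31 lists and the naming rule were fixed before the data were examined. The rule took the 12 genes with the largest fold in each direction past the adjusted threshold, without overlap between groups and with a mean CPM of at least 1. Where fewer than 5 passed in a direction, it took the 5 with the smallest p. It also took up to 4 listed members of each list with the smallest p, and 17 genes of lipid handling and AMPK whatever their result. Genes named as exceptions to a count, and the interferon-inducible genes of the closing section, were chosen after their values were seen. Some members of the lists are not reported here.

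Alternatives were RLE, upper-quartile and TMM factors computed from the listed genes, no count filter, a CPM of at least 1 in 3 samples, the replicate number as a block, DESeq2 1.42.0, limma-voom, stricter thresholds, camera with an estimated correlation, fry, and each library left out in turn. TMM as an alternative, and the list tests that combine leaving out PBS replicate 2 with an estimated correlation or with fry, were added after the data were seen. On simulated data for these 1386 genes with a biological coefficient of variation of 0.3, edgeR called 50% of genes changed 2-fold and 100% of genes changed 4-fold, with 3 of 1186 unchanged genes called. At 0.7, it called 0% of both. With PBS replicate 2 left out of the simulated counts, it called 29% and 99% at 0.3, and 0% of both at 0.7. Tables and figures used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.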

Results

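The transcriptome of intestinal epithelial cells was compared between 3 libraries from mice gavaged daily with Akkermansia muciniphila (Akk) for 7 weeks and 3 libraries from mice given PBS. The title of the series names lipid absorption and AMPK, the energy-sensing kinase, in the jejunum. The values analysed are those of 1386 genes that the authors selected as differing between these groups. Directions are those of the authors' deposited table, and a second test on the same libraries adds no independent evidence. The implied depth was 23561991 to 29374751 fragments per library. The listed genes took 13.05%, 23.6% and 11.98% of it in PBS replicates 1 to 3, and 15.5%, 16.8% and 13.3% in Akk replicates 1 to 3.

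Of the 1386 genes, 346 were listed as higher and 1040 as lower in Akk in the authors' deposited table. Among the genes listed as lower were 31 of 32 proliferation genes, 13 of 17 Paneth cell markers and 9 of 18 stem cell markers, while 4 apolipoprotein genes of chylomicron assembly were listed as higher. PBS replicate 2 stood apart from the other 5 libraries. It was the highest library for 1022 of the 1040 genes listed as lower, and exceeded the mean of PBS replicates 1 and 3 in these 1040 genes by a median of 5.55-fold. Its Pearson correlation of log2 CPM across the listed genes, which are not independent replicates, was 0.76 with PBS replicate 1 and 0.74 with PBS replicate 3, against 0.98 between these. The median fitted log2 fold change (Akk over PBS) of the genes listed as lower was -2.19 with all libraries and -0.78 without PBS replicate 2, and that of the genes listed as higher was 0.74 and 0.70.

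With the quasi-likelihood test of edgeR and Benjamini-Hochberg adjustment, 0 of the 1386 genes passed (smallest adjusted p = 0.0861). An unadjusted p under 0.05 was seen for 791, and DESeq2 called 786 (74 higher, 712 lower) and limma-voom 2. Without PBS replicate 2, edgeR called 270 genes, 24 higher and 246 lower, at a biological coefficient of variation of 0.29 in place of 0.71. It called 734 without PBS replicate 1 and 732 without PBS replicate 3. No overlap between the 3 Akk and 3 PBS libraries was seen for 901 of the 1040 genes listed as lower and 130 of the 346 listed as higher, where chance gives 10%, but the genes had been selected on these libraries. Factors computed from the listed genes moved the median log2 fold change of all genes from -1.85 to -0.15 (RLE), -0.63 (upper quartile) and -0.21 (TMM), and turned the sign of 204, 0 and 153 of the genes listed as lower.

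**Figure D1:**
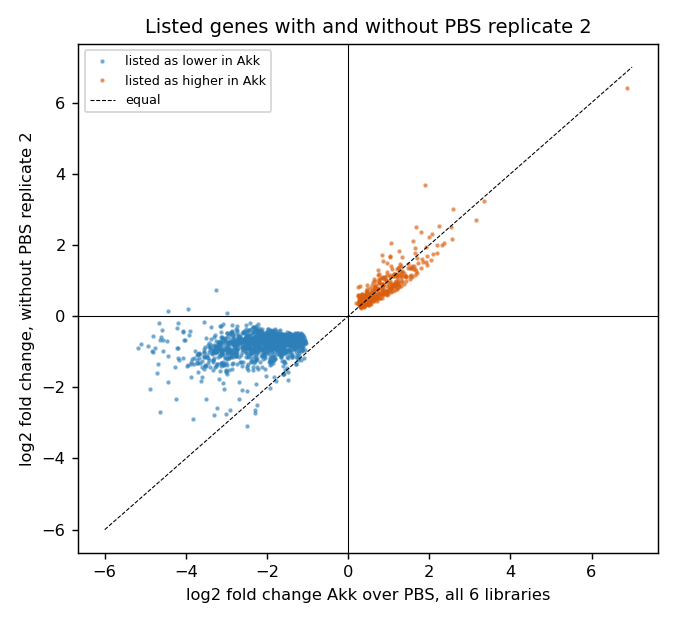
Fitted log2 fold change of Akk over PBS for the listed genes with all 6 libraries (horizontal axis) and without PBS replicate 2 (vertical axis), 1 point per gene, coloured by the direction in the authors' deposited table; Slc15a2, with 0 counts in PBS, is left out. Genes listed as lower shift from a median of -2.19 to -0.78, and genes listed as higher stay near the line of equal values (0.74 and 0.70).

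Of the 35 genes of lipid uptake and chylomicron assembly, 4 were listed, all as higher in Akk. Apoa4, an apolipoprotein of chylomicrons (chromosome 9, 46240696 to 46243459, plus strand, GRCm38), had an FPKM of 4415 ± 705 (SD, n = 3) in Akk and 1793 ± 1317 in PBS, a log2 fold change of 1.30 (SE 0.61). Apoc3, its neighbour on chromosome 9 (46232933 to 46235636, minus strand), had 763 ± 118 and 333 ± 219, and Apoc2 had 837 ± 134 and 375 ± 268 (SD, n = 3). Apob, the structural protein of the chylomicron (chromosome 12, 7977648 to 8016835), had 279.8 ± 27.1 and 162 ± 68.6. For each of the 4, all Akk libraries lay above all PBS libraries, and PBS replicate 2 was the lowest (467, 99.3, 122 and 91.6 FPKM for Apoa4, Apoc3, Apoc2 and Apob). None passed the edgeR test over all genes or adjusted over the list alone, with PBS replicate 2 or without it, and their median log2 fold change was 1.18, or 0.75 without PBS replicate 2, 1.92 with RLE and 1.90 with TMM factors. The fatty acid carriers and esterifying enzymes fixed for naming, Cd36, Fabp1, Fabp2, Mogat2, Dgat1 and Dgat2, as well as Mttp, Npc1l1 and Srebf1, were not listed.

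Of the 19 genes in the list of AMPK subunits and regulators, 3 were listed, all as lower in Akk. That list also holds the AMPK targets Acaca and Acacb, so Prkaa2 was its only listed subunit or regulator. Prkaa2, which encodes the alpha 2 catalytic subunit (chromosome 4, 105029874 to 105109890), had an FPKM of 1.29 ± 0.0683 in Akk and 3.28 ± 1.78 in PBS (SD, n = 3). Its log2 fold change was -1.34 (SE 0.61), but turned to 0.05 with RLE and 0.01 with TMM factors from the listed genes. Without PBS replicate 2 it was -0.81 (SE 0.20), past the edgeR threshold over all genes as 1 of the 3, and 2 passed adjusted over the list alone. Acaca and Acacb, the acetyl-CoA carboxylases that AMPK phosphorylates, had 0.672 ± 0.149 and 0.176 ± 0.0658 in Akk against 2.21 ± 1.65 and 0.933 ± 0.801 in PBS (SD, n = 3), each with its highest value in PBS replicate 2. With all libraries 0 of the 3 passed, over all genes or adjusted over the list alone. Prkaa1, Prkab1 and Prkag1, which encode other subunits, were not listed. These are transcript levels, and AMPK activity was not measured in them.

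Genes of fatty acid oxidation and ketogenesis were listed in both directions, 3 higher and 4 lower of 32. Cpt1a, the rate-limiting enzyme of mitochondrial fatty acid import, had an FPKM of 8.39 ± 0.978 in Akk and 34.9 ± 30.3 in PBS (SD, n = 3; 69.9 in PBS replicate 2). Ppara, a lipid-sensing nuclear receptor, had 1.94 ± 0.591 and 5.03 ± 2.10, and Acadl, an acyl-CoA dehydrogenase, 31.1 ± 8.36 and 65.1 ± 9.48. Vnn1, a pantetheinase, had 57.7 ± 27.6 in Akk and 26.2 ± 9.41 in PBS. With all libraries 0 of the 7 passed the edgeR test over all genes or adjusted over the list alone. Without PBS replicate 2 the counts were 3 and 5, with log2 fold changes of -1.06 (SE 0.19) for Cpt1a and -0.94 (SE 0.25) for Acadl, both past the threshold over all genes. Acadl and Eci2 turned positive with RLE and with TMM factors, as did the median of the list (0.21 and 0.17). The camera direction of the list was up (adjusted p = 0.375) while its median log2 fold change was -1.03.

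All 6 listed genes of fatty acid synthesis, of 17, were lower in Akk in the authors' deposited table. They include Acaca, which is also in the AMPK list. Fads2 and Fads1, the desaturases of polyunsaturated fatty acids, had an FPKM of 2.85 ± 0.596 and 0.594 ± 0.146 in Akk against 32.3 ± 42.9 and 5.28 ± 7.61 in PBS (SD, n = 3), with 81.9 and 14.1 in PBS replicate 2. Scd2, a stearoyl-CoA desaturase, had 4.30 ± 0.280 and 12.1 ± 7.12, and Lpin1, a phosphatidate phosphatase, 0.504 ± 0.128 and 2.06 ± 2.01. The list's median log2 fold change was -1.85, or -0.79 without PBS replicate 2, and -0.16 with RLE and -0.21 with TMM factors. Camera gave adjusted p = 0.2995 (range over all camera alternatives 0.192 to 0.755). By edgeR 0 of the 6 passed over all genes or adjusted over the list alone, and without PBS replicate 2 the counts were 2 and 4; Fasn turned positive with RLE factors. Of the genes of cholesterol synthesis, Insig1 and Sc5d were listed as higher, and neither passed over all genes or adjusted over the list alone.

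The 53 listed crypt markers were all listed as lower, and each was highest in PBS replicate 2; 4 of 17 Paneth, 9 of 18 stem cell and 1 of 32 proliferation markers were not listed. Over the 13 Paneth cell markers PBS replicate 2 exceeded the mean of PBS replicates 1 and 3 by a median of 35.4-fold, over the 31 proliferation genes 10.9-fold and over the 9 stem cell markers 7.78-fold. Defa23, a Paneth cell defensin, had an FPKM of 7.59 ± 1.55 in Akk and 274 ± 449.9 in PBS (SD, n = 3), of which PBS replicate 2 had 793. Olfm4, a marker of crypt base stem cells, had 5.03 ± 1.35 and 172 ± 283 (498 in PBS replicate 2), and Top2a, the topoisomerase of dividing cells, 1.79 ± 0.239 and 24.6 ± 36.7 (67.0 in PBS replicate 2). Median log2 fold changes were -4.18 for Paneth markers, -2.98 for stem cell markers and -3.05 for proliferation genes, and -0.45, -0.92 and -0.80 without PBS replicate 2, where the Paneth markers Defa30 and Itln1 turned positive. They were -1.59, -0.85 and -0.88 with RLE and -1.73, -0.94 and -0.97 with TMM factors. By edgeR 0 passed over all genes, and 13, 9 and 31 passed adjusted over the list alone, on genes that had been selected on these libraries. Without PBS replicate 2 the counts over all genes were 0, 4 and 8, and those adjusted over the list alone 0, 6 and 13. Camera gave adjusted p = 0.406, 0.295 and 0.0629 for Paneth, stem cell and proliferation genes. The ranges over all camera alternatives were 3.15e-05 to 0.931, 0.00343 to 0.755 and 0.000159 to 0.755. Camera without PBS replicate 2 gave adjusted p = 0.862, 0.158 and 0.0182, and 0.931, 0.584 and 0.584 with an estimated correlation.

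**Figure D2:**
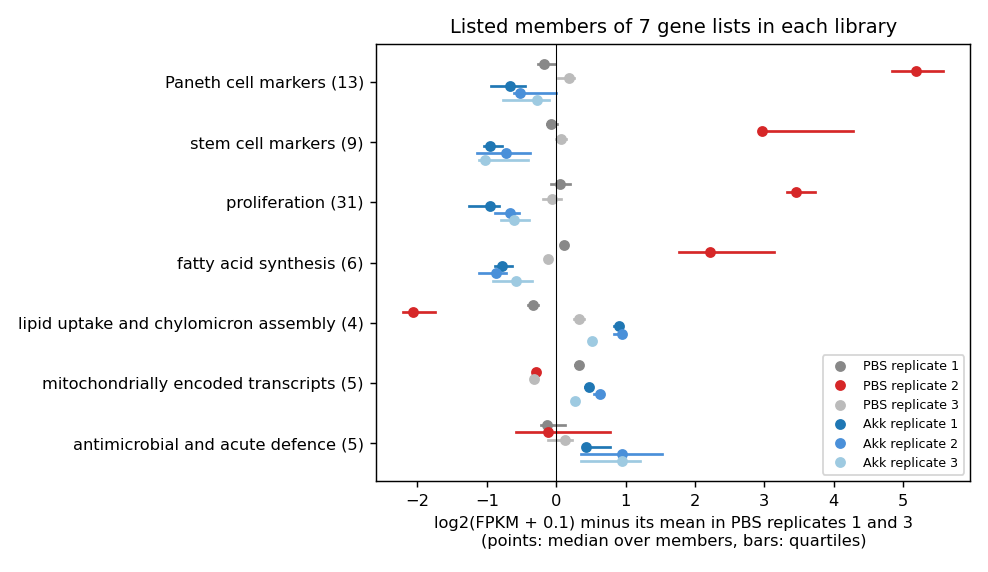
Median (points) and quartiles (bars) over the listed members of 7 gene lists of log2(FPKM + 0.1) minus its mean in PBS replicates 1 and 3, for each of the 6 libraries; the number of listed members is in parentheses. PBS replicate 2 lies far to the right for Paneth, stem cell, proliferation and fatty acid synthesis genes and to the left for lipid uptake genes.

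Camera moved 2 of the 8 lists with at least 5 listed members, both up relative to the other listed genes, most of which were listed as lower. The antimicrobial and acute defence list had 5 listed members, 4 higher and 1 lower in Akk, with a median log2 fold change of 0.77, or 1.98 with RLE and 1.96 with TMM factors (adjusted p = 0.00207; adjusted p = 0.191 with an estimated correlation; range over all alternatives 0.00089 to 0.401). Its members Reg3b and Reg1, secreted C-type lectins, had an FPKM of 1756 ± 499 and 154 ± 39.96 in Akk against 1028 ± 402 and 71.7 ± 21.5 in PBS (SD, n = 3), and Saa1, an acute-phase protein, 6.78 ± 2.48 against 1.74 ± 1.62. Ang4, a Paneth cell ribonuclease, was the member listed as lower, with 30.8 ± 5.70 against 465 ± 728, of which PBS replicate 2 had 1305. The 5 mitochondrially encoded transcripts listed, of 13, were all higher, with a median log2 fold change of 0.52, or 1.48 with RLE and 1.46 with TMM factors (camera adjusted p = 0.000111; adjusted p = 0.444 with an estimated correlation; range over all alternatives 1.81e-07 to 0.584). Of these, mt-Nd4, a subunit of respiratory complex I, had 11155 ± 1269.6 in Akk and 7626 ± 1954 in PBS (SD, n = 3). No member of either list passed the edgeR test over all genes or adjusted over the list alone. The ileal and colonic identity list (2 higher, 3 lower of 20; camera adjusted p = 0.375, direction up at a median of -1.19) did not pass, and its median turned to 0.25 with RLE and 0.20 with TMM factors; without PBS replicate 2, 1 member (Car4) passed the edgeR test over all genes.

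The genes with the smallest p in each direction, none past the adjusted threshold, included Slc15a2, a proton-coupled peptide transporter (chromosome 16, 36750177 to 36784962, minus strand). It had 0 counts in all 3 PBS libraries and 135, 439 and 151 counts in Akk, at least 74.97-fold higher against a floor of 3 counts per library (44.5-fold without Akk replicate 2), a limit that covers counting error only. Gm28040 had an FPKM of 3.09 ± 1.43 in Akk and 0.529 ± 0.0754 in PBS, and Cyp3a44, a cytochrome P450, 1.05 ± 0.687 and 0.193 ± 0.106 (SD, n = 3). Of the unnamed loci, newGene_3245 (2.21 ± 0.412 against 0.0157 ± 0.0272) and newGene_4894 were higher and newGene_214 was lower. Ifitm3, an interferon-induced membrane protein (chromosome 7, 141009586 to 141010770, minus strand), had 4.25 ± 1.20 in Akk and 60.5 ± 50.3 in PBS (SD, n = 3), and 31.5 in PBS without replicate 2. Pir, an iron-binding nuclear protein, had 0.199 ± 0.120 and 1.45 ± 0.449, and Tcf23 0.180 ± 0.00916 and 1.20 ± 0.485. Hnrnpa3, an RNA-binding protein, had 234, 227 and 232 counts in Akk against 1252, 3164 and 1443 in PBS, a log2 fold change of -3.22 (SE 0.63), where the ratio of mean FPKM gave -1.65. Of these 10 genes, 9 passed the edgeR test without PBS replicate 2, all but Cyp3a44 (adjusted p = 0.0565), with log2 fold changes of -2.88 (SE 0.29) for Ifitm3 and -2.58 (SE 0.19) for Hnrnpa3. For Hnrnpa3 the counts again gave a larger difference than FPKM, whose mean was 3.38 in Akk and 6.83 in PBS replicates 1 and 3.

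**Figure D3:**
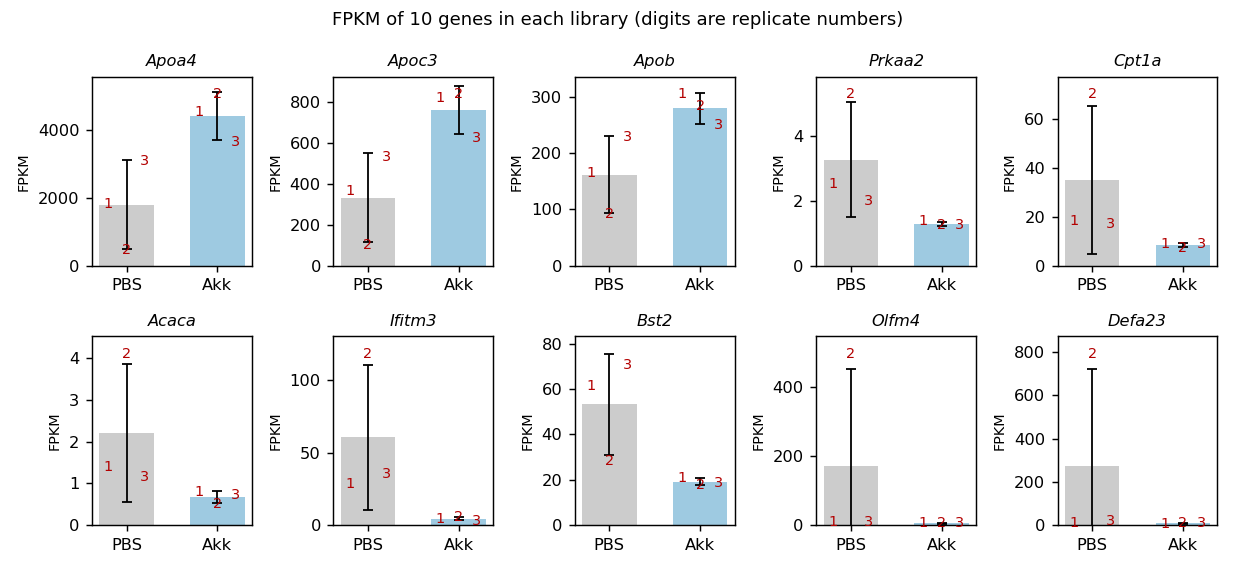
FPKM of 10 genes in PBS and Akk; bars are means, error bars SD (n = 3, lower ends stop at the axis) and digits mark the replicate. For Apoa4, Apoc3 and Apob the Akk libraries lie above the PBS libraries, and for Olfm4 and Defa23 the PBS mean is set by replicate 2 (498 and 793 FPKM).

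Other fixed lists had few listed members, and none of these passed the edgeR test over all genes with all 6 libraries; without PBS replicate 2, Bst2, Nqo1, Cldn2, Gcg and Asns did, all lower. The type I interferon list had Bst2 and Ifit2 (2 of 28), both lower and both past the threshold adjusted over the list alone; Bst2, which tethers enveloped viruses, had an FPKM of 19.0 ± 1.52 in Akk and 53.4 ± 22.3 in PBS (SD, n = 3). Of the clock genes, Npas2, Cry1 and Bhlhe40 were higher, with log2 fold changes of 1.26 (SE 0.62), 1.05 (SE 0.61) and 0.49 (SE 0.44). Goblet cell markers Muc13 and Zg16 (2 of 17) were higher. So were the duodenal genes S100g, Slc40a1 and Cybrd1 (3 of 17), whose values were highest in Akk replicate 3 (97.7 FPKM for S100g, against 5.58 and 12.9 in Akk replicates 1 and 2). Of the enteroendocrine markers, Gip and Sst were higher and Gcg was lower (3 of 24). Of the xenobiotic and retinoid genes, Cyp1a1 and Bco1 were higher and Nqo1 was lower (3 of 31). Of tight junction genes Amotl2 was higher and Cldn2 lower (2 of 22), and of sugar and peptide absorption genes G6pc was higher and Slc1a1 lower (2 of 28). Fosb was higher and Myc lower among immediate early genes (2 of 24), and Asns (unfolded protein response, 1 of 24) and Deptor (autophagy and mTORC1, 1 of 29) were lower. Clps, pancreatic colipase, the single listed contaminant marker of 21, had a log2 fold change of -3.25 that turned to 0.75 without PBS replicate 2. Adjusted over the list alone, Cldn2, Myc and Asns passed, 1 gene in each list, and for ileal and colonic identity 2 members did. Asns was the single listed member, so its p was unadjusted, and Cldn2 and Myc were each adjusted over 2 selected genes. The counts without PBS replicate 2 were 0 for immediate early genes (Myc no longer passed), 1 each for the lists of Cldn2 and Asns, 5 of 5 for ileal and colonic identity, 3 of 3 for enteroendocrine markers, 2 of 3 for xenobiotic and retinoid genes and 2 of 2 for type I interferon. No member was listed of the lists for bile acid handling, MHC class II, tuft cells, T cells and intraepithelial lymphocytes, B and plasma cells, myeloid cells, stromal cells and the nuclear-encoded respiratory chain.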

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

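The count of genes past the threshold depended on the libraries and on the tool. The count of 0 with edgeR became 6 with the replicate block (2 higher, 4 lower), 2 with limma-voom (2 higher) and 786 with DESeq2 (74 higher, 712 lower; 262 of the 1386 adjusted p were NA). Leaving out each library in turn gave 0 to 734 genes, 0 to 27 higher and 0 to 723 lower: 734 without PBS replicate 1, 270 without PBS replicate 2, 732 without PBS replicate 3, and 0 without each Akk replicate. RLE, upper-quartile and TMM factors and the stricter thresholds gave 0. The filters on low counts removed no gene, so they say nothing about stability. The 2 lists moved became 4 with RLE and 4 with TMM factors from the listed genes, 5 with the replicate block, 0 with an estimated correlation (also without PBS replicate 2), 1 with fry and 4 with fry without PBS replicate 2; the cause was not tested. Same-numbered deviations from the group means correlated at 0.24, -0.05 and -0.29, and not every sample correlated best with its own number. This check cannot tell whether the numbers pair the samples, because PBS replicate 2 sets the deviations of PBS replicates 1 and 3 alike. They correlated at 0.24 and 0.30 with Akk replicate 1, and at -0.22 and -0.29 with Akk replicate 3. Reversed values were log2 fold changes of Prkaa2 (0.0472 with RLE, 0.00573 with TMM) and Acadl (0.0583 and 0.0271), and of Clps (-3.81 to 0.75 over the left-out libraries, reversed without PBS replicate 2). The turns of Prkaa2 and Acadl are favoured by factors computed from genes mostly listed as lower. Fry tests a list against no change, and camera against the other listed genes, most of which were listed as lower. Their directions therefore differed for fatty acid oxidation (median -0.98, and -0.74 without PBS replicate 2) and ileal and colonic identity (-1.03 and -0.60), down by fry and up by camera at the same medians. Fry without PBS replicate 2 called stem cell markers (adjusted p = 0.00619), and proliferation and fatty acid synthesis (0.0262 each), whose listed members had all been selected as lower. With the replicate block camera called Paneth cell markers (adjusted p = 3.15e-05), stem cell markers (0.00343) and proliferation (0.000159), at the preset correlation and in samples whose pairing by number is not known. With an estimated correlation, without the block, these lists had adjusted p = 0.818, 0.755 and 0.755. TMM had been chosen before the data were examined as the normalization of the tests; its use as an alternative, and the list tests that join fry or an estimated correlation with leaving out PBS replicate 2, were added after the data were seen. In simulation with 3 libraries against 3 at a biological coefficient of variation of 0.7, near that of all 6 libraries, edgeR called 0% of 4-fold changes. DESeq2 called 23% of them, and 9 of 1186 unchanged genes. At 0.3, near that without PBS replicate 2, and with that library left out of the simulated counts, edgeR called 29% of 2-fold and 99% of 4-fold changes. The simulated spread was independent between genes and equal in all libraries. In the data 1 library stands apart with many genes moving together, so the simulation does not show why edgeR called 0 genes here.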

Other observations

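The tests on PBS replicate 2, on the interferon-inducible genes and on other splits of the libraries were chosen after the results were seen. Interferon-inducible genes outside the type I list were also listed as lower in Akk. Of 71 such genes, a list drawn up after the data were seen that includes the type I list, 12 were listed. All were lower in the authors' deposited table, as were 1040 of all 1386 listed genes: Ifitm2, Ifitm3, Ly6a, Ly6e, Bst2, Ifi27l2a, Plscr1, Irgm1, Tor3a, Slfn9, Tspo and Ifit2. Each of the 12 was lower in every Akk library than in PBS replicates 1 and 3, but not always than in PBS replicate 2: there Ifi27l2a had 0.532 FPKM, below all Akk libraries (3.24 to 4.58), and Ifit2 had 3.60, below Akk replicate 3 (3.91). This is not particular to the interferon-inducible genes: 901 of the 1040 genes listed as lower had every Akk library below every PBS library. PBS replicate 2 lay below the mean of PBS replicates 1 and 3 in 6 of the 12, Ifi27l2a, Ifit2, Ly6a (12.3 against 32.1 FPKM), Bst2 (28.2 against 66.0), Ly6e and Irgm1. Ly6a, a GPI-anchored surface protein, had an FPKM of 5.22 ± 0.759 in Akk and 25.5 ± 11.5 in PBS (SD, n = 3), Ly6e 38.1 ± 6.22 and 126 ± 16.95, and Irgm1, an immunity-related GTPase, 31.8 ± 5.95 and 70.04 ± 12.1. Their median log2 fold change was -2.04 (-0.98 with RLE and -1.04 with TMM factors from the listed genes), and 10 of the 12 passed the edgeR test without PBS replicate 2. With these factors Tor3a and Tspo turned positive.

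Of 85 ribosomal protein genes found by name in the annotation, 71 were listed, all as lower in Akk, as were 1040 of all 1386 listed genes. Their median log2 fold change was -1.90 and, without PBS replicate 2, -0.80 (quartiles -0.91 and -0.71, 51 past the edgeR threshold), against -2.19 and -0.78 for all genes listed as lower. PBS replicate 2 exceeded the mean of PBS replicates 1 and 3 by a median of 4.22-fold in them, and with RLE and TMM factors their median was -0.17 and -0.23, with 11 and 7 of the 71 positive. The group was chosen after the data were seen, and no test set it against the other genes.

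Genes listed as lower in Akk were highest in PBS replicate 2. A difference in depth or scaling of that library would move all genes alike. Its median log2 ratio to PBS replicates 1 and 3 differed by 5.75 between the 53 crypt list members and the 4 lipid genes, which lay at -2.11. The sign of this difference is favoured by the choice of genes, because the crypt members were listed as lower and the lipid genes as higher. A single factor alone would leave no such difference, but a factor together with other changes stays open. A larger share of crypt cells in that library stays open. Crypt list members exceeded the other genes listed as lower by 1.24 in median log2 ratio, but this restates what raised the question, in genes of a single library that move together, so it decides nothing. A swap with an Akk library cannot be told apart by correlation, because the listed genes were chosen on the labelled groups, which keeps Akk libraries alike (lowest correlation between them 0.944, against 0.939 for the closest Akk and PBS replicate 1 or 3 pair). PBS replicate 2 correlated at 0.52 to 0.60 with the Akk libraries, below its 0.74 and 0.76 with the other PBS libraries, which runs against a swap but is also favoured by that choice of genes. Differences in dissection or gut segment between animals stay open and were not tested.

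The lower interferon-inducible genes were weighed against the same library. Without that library their median log2 fold change was still -1.60 (quartiles -2.65 and -1.19, median SE 0.24), with 10 of the 12 past the edgeR threshold. This contrast leaves PBS replicate 2 out, so crypt cells in that library cannot enter it, whatever the values. A difference in crypt cells between Akk and PBS replicates 1 and 3 was not excluded. Listed stem cell markers and proliferation genes also stayed lower without PBS replicate 2 (median log2 fold changes -0.92 and -0.80). That the interferon-inducible genes stayed lower is favoured by their selection on these libraries: 1036 of all 1040 genes listed as lower stayed below 0 without PBS replicate 2. Scaling of the libraries stays open. Of the other 1028 genes listed as lower, 2.72% lay at or below the interferon-inducible median of -1.60, but this is fixed in part by the choice of genes. The interferon-inducible list was drawn up after the data were seen. The other genes were mostly highest in PBS replicate 2 (1022 of all 1040), so their fold changes shrink without it. The treatment, and differences of cage or litter, stay open and were not tested. None of the 60 markers of immune cells in the fixed lists was listed, which excludes nothing.

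Chance cannot be excluded or shown with 3 libraries against 3, because there are only 10 splits and no share under 0.05 can be reached. All 10 splits called 0 genes by the adjusted edgeR test, the highest of the other splits being 0; at an unadjusted p under 0.05 the real split had 791 genes and the highest of the others 241, in genes selected on the real split. For the gene lists, 8 of the 10 splits moved at least the 2 of the real split, and the highest of the others moved 6. These counts rest on the preset correlation: with an estimated correlation 0 lists moved in the real split and 0 at most in the others.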
